A study of Oryza sativa with 6 samples.

How the data were processed

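Galls and uninfected meristematic root fragments of rice variety Nipponbare, grown hydroponically, were each represented by 3 samples of total RNA, and each sample was hybridised to 1 Affymetrix rice array with biotin-labelled, amplified cRNA (20 µg). Per the labels, seedlings 6 days old were inoculated with 300 juveniles, and galls of 45 plants were collected 144 hours, or 6 days, later. Another label field gives a different time with the inoculation, and what it refers to is not given in the sources used here. RNA amounts were 16, 17 and 35 µg for uninfected root replicates 1, 2 and 3, and 6, 17 and 35 µg for gall replicates 1, 2 and 3. The labels name separate samples and harvests but no separate plants for the uninfected root, so p-values measure the spread between these samples.

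The deposited values are the authors' log2 values after GCRMA in R 2.6.2, per the submitters' processing notes. GCRMA corrects the background with the probe sequences, normalises quantiles between arrays and summarises the probes of a probe set. The log2 scale was read from the values themselves, which ran from 1.02 to 16.1 with array medians of 2.87 to 2.93, and genes were not centred. Further settings were not given in the sources used here, and scanner files were not used here. Quantile normalisation makes the value distributions of the arrays alike, so a shift shared by most genes would not be seen. The table held 57381 probe sets, of which 123 control probe sets were left out of the tests. No filter on dim probe sets was applied, and a value under 4 was taken as dim. Of the 142 called genes among those named, 33 had a mean under 4 in the lower group, where the size of the difference is less certain. For arrays, the number of samples sets the precision, which was 3 against 3 here.

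Probe sets were named through a table of the array's platform annotation, which can be old, and symbols were updated through gene identifiers with a RefSeq gene table of assembly ASM3414082v1, whose coordinates were not used because the array files name no build. Of the tested probe sets, 22436 had 1 gene, 95 had several and 34727 were unnamed here. They covered 17905 genes, all found in the gene table, of which 3444 had over 1 probe set and were represented by the probe set with the highest mean over the 6 arrays. Only 2452 genes had a symbol or synonym, so named genes are a minority of the changed ones. Probe sets of the _x_at and _s_at kinds can react with related transcripts, and those of OsORC4, OsAHP1, OsRR4, OsKS1A, OsMT2a and OsNIP2-2 are of these kinds.

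Galls were compared with uninfected root by a linear model per probe set in limma 3.58.1 under R 4.3.3, with moderated variances that follow the mean (lmFit, eBayes with trend), two-sided, and Benjamini-Hochberg adjustment over 57258 probe sets at 0.05. Gene lists were tested with camera, also in limma, with a preset inter-gene correlation of 0.01 on 1 probe set per gene, for lists with at least 3 measured genes, and adjusted over the 34 lists tested. Tests, alternatives, the rule for named genes and the subjects of 37 lists were fixed before the data were examined, with gene descriptions meant for both the rule and the lists. The tables given hold no gene descriptions, so the rule's need for a description became one for a symbol or synonym, and list members were taken from gene symbols and synonyms after the tables were read and before any value was tested, and 3 lists were left with under 3 genes. A further 11 lists of families seen in the annotation were added at that point and adjusted as a family of their own. The measured genes of a list are therefore only those with a matching symbol or synonym. Family members without one were not counted, so list sizes do not show how much of a family the array covers. Lists overlap, with 1109 genes in 1 or more of them, and the xylem list shares its cellulose synthases with another.

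Named genes were the 10 with the largest rise and the 10 with the largest fall among genes with an adjusted p under 0.05, the same direction in all 3 same-numbered pairs, a mean of at least 4 in the higher group and a symbol or synonym. To reach them, 23 rising and 14 falling genes without a name were passed over. From each list up to 2 members that rose most and up to 2 that fell most were also taken, and 16 genes were chosen after their values were seen, as stated where they appear, except OsARF2, which the list rule takes as well.

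Same-numbered samples of the groups share a harvest day in the labels, so the numbers pair them. The correlation of deviations from the group means over probe sets with a mean of at least 4 was 0.186, -0.186 and 0.0742 for numbers 1, 2 and 3, against -0.334 to 0.338 between different numbers. The fit without the number as a block was chosen before the data were examined, and the fit with it is an alternative. Other alternatives were leaving out each array and each pair, a minimum mean of 4, no variance trend, a robust prior, no moderation, quantile normalisation, median centring, 1 probe set per gene and array weights. The default estimate of array weights did not converge, and the gene-by-gene method was used. The procedure was tested on simulated data of 57258 probe sets in 5 simulations of this comparison. It recovered 1.79% of 335 changes of 0.5 log2, 39.1% of 335 changes of 1 log2 and 77.9% of 330 changes of 2 log2. Of its calls, 6.19% were false. The changed probe sets were a far smaller share than the 9.38% called in the real data, and all had a mean of at least 4. Simulated noise was normal and independent between probe sets. The recovered shares therefore do not give the sensitivity of the real comparison. Tables were read and plots drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.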

Results

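Transcript levels were measured with Affymetrix rice arrays in roots of Oryza sativa, variety Nipponbare, after infection by the root-knot nematode Meloidogyne incognita. This parasite settles in the root, where host cells around its head become enlarged, multinucleate giant cells and the surrounding tissue swells into a gall. The series held 6 arrays in 2 groups. 3 arrays carried RNA of galls harvested 144 hours after inoculation with 300 infective juveniles, each from 45 plants, and 3 carried RNA of meristematic fragments of uninfected roots. Values were the authors' GCRMA log2 values of 57258 rice probe sets, and 38.5% to 39.0% of them reached 4 on each array. The number of arrays, 3 per group, limits the precision of every difference.

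Galls were compared with uninfected root fragments to find rice genes whose transcript levels differ early in a compatible interaction. The uninfected fragments were meristematic, so infection and sampled root zone go together in this design. Rises, falls and list shifts alike therefore cannot be assigned to the nematode apart from the zone. OsIRX9, of xylan synthesis, OsWOX11, of root meristems, and the chitinases OsChia2a and OsCht11 rose by over 3 log2 in galls. The actin depolymerising factors OsADF1, OsADF6 and OsADF9 and the secondary wall cellulose synthase OsCesA9 fell by over 3 log2. In all, 2925 probe sets were higher and 2446 lower than in uninfected root at an adjusted p under 0.05 (limma), of which 1345 and 1268 differed by at least 2-fold. By gene, with 1 probe set each and the same adjustment, 1815 of 17905 genes were higher and 1588 lower. The list counts below are by gene and are to be set against these shares. Called probe sets made up 9.38% of those tested, and each of them differed in the same direction in all 3 same-numbered pairs of arrays. That agreement adds little, because a call with 3 arrays per group already needs well-separated groups. Arrays of one group correlated with r from 0.970 to 0.994 over probe sets with a mean of at least 4, and arrays of different groups with r from 0.908 to 0.941. Uninfected root replicate 3 stood apart within its group, with an SD of deviations from the group mean of 0.341 against 0.143 to 0.242 in the other 5 arrays. Without it, 3387 probe sets were higher and 3479 lower. Gall replicate 3 had lower hybridisation controls (mean 9.57 log2) than the other 5 arrays (10.3 to 10.6), and without it 1893 were higher and 1464 lower. The counts were also over 1.5 times lower without uninfected root replicate 1 (1699 and 1482), gall replicate 1 (1725 and 1439) or gall replicate 2 (1877 and 1431).

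Among named genes, OsIRX9 (LOC4344394), a glycosyltransferase of the family that makes the xylan backbone, rose most, from 3.19 ± 0.50 in uninfected root to 8.61 ± 0.21 in galls (log2, SD, n = 3), by 5.41 (SE 0.26, adjusted p = 0.000143). OsChib3H-a (LOC4351194), known as a xylanase inhibitor of chitinase ancestry, rose by 4.28 (SE 0.27, adjusted p = 0.000364). The chitinases OsChia2a (LOC4349267) and OsCht11 (LOC4331519) rose by 4.01 (SE 0.19) and 3.85 (SE 0.17). OsWOX11 (LOC4344325), a homeobox factor required for crown root growth, rose from 2.85 ± 0.10 in uninfected root to 6.70 ± 0.47 in galls, by 3.86 (SE 0.23, adjusted p = 0.000317). Rises of similar size were measured for the ALOG-domain gene OsG1L1 (LOC4328416, 4.23, SE 0.22), the glutaredoxin gene OsGRXS3 (LOC4327691, 4.22, SE 0.12) and the receptor-like kinase gene OsCRK10 (LOC4343501, 4.10, SE 0.23). OsACO1 (LOC4347225, 4.09, SE 0.32), an ACC oxidase of the last step of ethylene synthesis, and the dehydrin gene OsRAB16D (LOC4350451, 4.04, SE 0.32) rose as well. Adjusted p of these 10 genes lay between 4.99e-05 and 0.000888. The uninfected root means of OsGRXS3 (2.75) and OsWOX11 lay below the array medians (2.87 to 2.93), and those of OsIRX9, OsG1L1, OsCRK10 and OsRAB16D were under 4 and so dim, which leaves the sizes and order of these rises uncertain.

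Among named genes, the 10 deepest falls included those of 3 actin depolymerising factors and of several wall genes. OsADF9 (LOC4343240) decreased from 8.91 ± 0.34 in uninfected root to 2.49 ± 0.23 in galls and so fell by 6.41 (SE 0.20, adjusted p = 5.96e-05), and OsADF1 (LOC4330233, -5.46, SE 0.28) and OsADF6 (LOC4336623, -4.72, SE 0.20) fell. OsBC1 (LOC4333114), the COBRA-like protein whose loss makes culms brittle, fell by 5.31 (SE 0.22, adjusted p = 9.63e-05), and the secondary wall cellulose synthase OsCesA9 (LOC4347093) fell by 3.80 (SE 0.21, adjusted p = 0.000237). OsCslD1 (LOC4349505), a cellulose synthase-like gene needed for root hair growth, decreased from 7.69 ± 0.36 in uninfected root to 3.55 ± 0.16 in galls and so fell by 4.14 (SE 0.20, adjusted p = 0.000142). The endo-1,4-beta-glucanase OsGLU6 (LOC4337384) fell by 6.11 (SE 0.51), the beta-expansin OsEXPB18 (LOC4338206) fell by 4.60 (SE 0.22) and the beta-glucosidase OsBGLU30 (LOC4347441) fell by 5.09 (SE 0.52). OsILL3 (LOC4334707), named as a hydrolase of auxin conjugates, varied more between arrays and fell by 5.66 (SE 0.93, adjusted p = 0.0135). Its adjusted p was 0.0738 with the replicate number as a block, the only call among these 20 genes that the block ended. The OsADF9 mean in galls lay below the array medians (2.87 to 2.93), where GCRMA values hold little signal above background, and the gall means of OsILL3, OsBGLU30, OsADF6, OsCslD1 and OsCesA9 were under 4, so the sizes and order of these falls are uncertain.

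**Figure D1:**
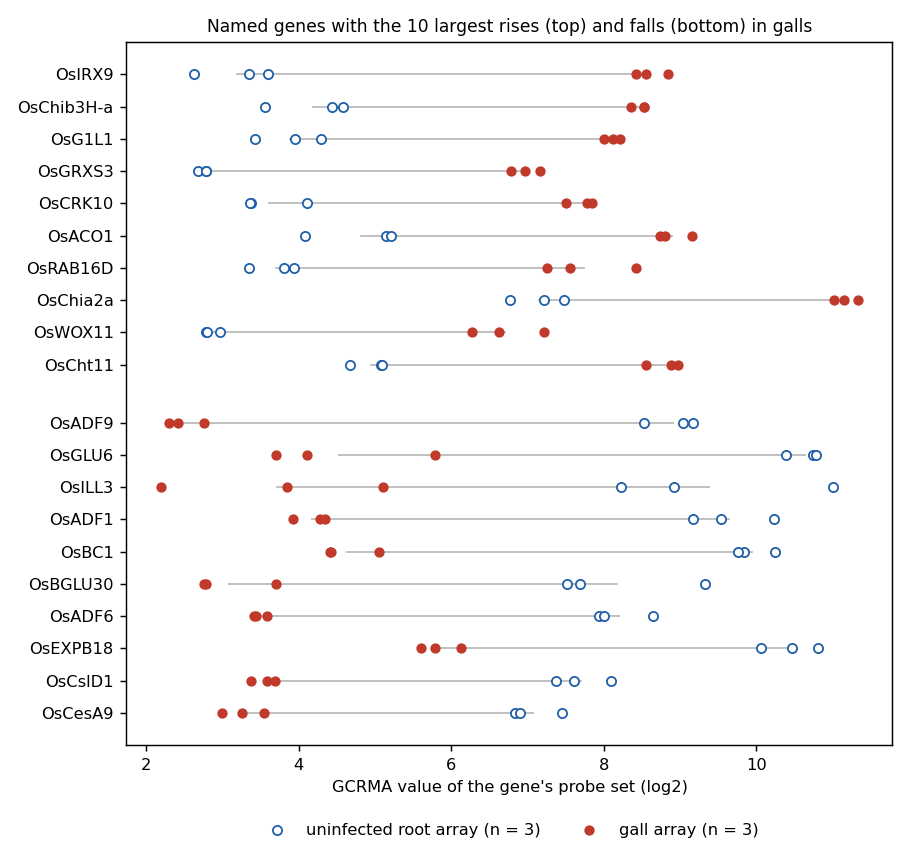
Values of the named genes with the 10 largest rises (upper block) and the 10 largest falls (lower block) in galls. The x axis is the authors' GCRMA value of the gene's probe set on a log2 scale, each open blue circle is 1 uninfected root array, each filled red circle is 1 gall array (n = 3 per group), and grey lines join the group means. In each of the 20 genes all 3 gall arrays lie on one side of all 3 uninfected root arrays, which the rule that selected them favours.

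Some meristem homeobox genes and some cell cycle genes rose in galls. Here and below, measured genes are those with a matching symbol or synonym, and members of a family without one were not counted. Of the 13 measured KNOX and WOX genes, 6 rose, 0 fell and 7 did not pass (6 higher and 0 lower adjusted over the list alone, 6 and 0 at an unadjusted p under 0.05, camera adjusted p = 0.0246). The list did not pass with an estimated correlation (adjusted p = 0.585), without uninfected root replicate 2 (0.0526) or without gall replicate 3 (0.104). Besides OsWOX11, OsWOX6 (LOC4332705) rose by 2.95 (SE 0.30, adjusted p = 0.00219). The other 4 that rose, OsWOX13 (LOC4327441, 1.18, SE 0.11) and the KNOX genes OSH6 (LOC4325788, 2.47, SE 0.26), OSH1 (LOC4333973, 1.54, SE 0.09) and OSH71 (LOC4337701, 1.24, SE 0.15), were singled out after their values were seen, and the uninfected root means of OSH6 and OSH1 were under 4. Of the 21 measured D-type cyclins, CDK inhibitors and partners, 5 rose, 0 fell and 16 did not pass (6 higher and 0 lower adjusted over the list alone, 8 and 2 at an unadjusted p under 0.05, camera adjusted p = 0.125). OsSMR1 (LOC4349289), a SIAMESE-related inhibitor of cyclin-dependent kinases, rose by 2.88 (SE 0.14, adjusted p = 0.00014), and the cyclin gene OsCYCD3-2 (LOC4346394) by 2.69 (SE 0.24, adjusted p = 0.00137). Of the 36 measured genes of DNA replication and H2B histones, 4 rose, 0 fell and 32 did not pass (11 higher and 0 lower adjusted over the list alone, 12 and 0 at an unadjusted p under 0.05, camera adjusted p = 0.0246). The list did not pass with an estimated correlation (adjusted p = 0.656), among genes with a mean of at least 4 (0.0695), without uninfected root replicate 2 (0.126) or without gall replicate 3 (0.123). The largest rises there were those of OsORC4 (LOC4324139), a subunit of the origin recognition complex, by 0.69 (SE 0.13) and OsH2B.10 (LOC4324495) by 0.59 (SE 0.10). OsORC4 lost its call with the replicate number as a block (adjusted p = 0.0521) and without uninfected root replicate 1 or gall replicate 1, 2 or 3 (adjusted p from 0.0523 to 0.0798). OsH2B.10 lost its call with the replicate number as a block (adjusted p = 0.0783) and without gall replicate 3 (adjusted p = 0.056). Of the 47 measured mitotic genes, 8 rose, 6 fell and 33 did not pass (14 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.366). The B-type cyclin gene OsCycB1-1 (LOC4326914) rose by 0.93 (SE 0.20) and the kinesin gene OsKIN10C (LOC4339007) by 0.87 (SE 0.16), while OsNek3 (LOC4342542, -1.51, SE 0.18) and the kinesin gene OsKIN14B (LOC9267695, -1.39, SE 0.18) fell. The uninfected root mean of OsCycB1-1 was under 4. OsCycB1-1 lost its call without uninfected root replicate 1 or 2 or gall replicate 1 or 3 (adjusted p from 0.0715 to 0.119). OsKIN10C lost its call without uninfected root replicate 1 or gall replicate 1, 2 or 3 (adjusted p from 0.0633 to 0.0748).

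Expansins, endoglucanases and cellulose synthases each had members that rose and members that fell. Of the 29 measured expansin genes, 9 rose, 7 fell and 13 did not pass (9 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.557). OsEXPA6 (LOC4332763) and OsEXPA7 (LOC4334606) rose by 3.79 (SE 0.46) and 2.92 (SE 0.11), whereas OsEXPB18 (-4.60, SE 0.22) and OsEXPA1 (LOC4335222, -3.04, SE 0.25) fell. Of the 14 measured endo-1,4-beta-glucanase genes, 5 rose, 3 fell and 6 did not pass (6 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.471). OsCel9E (LOC4330637) and OsCel9C (LOC4338100) rose by 3.28 (SE 0.11) and 2.44 (SE 0.13), whereas OsGLU6 fell by 6.11 and OsGLU10 (LOC4330667) fell by 1.00 (SE 0.17). The uninfected root mean of OsCel9E was under 4. OsGLU10 lost its call with the replicate number as a block (adjusted p = 0.064) and without gall replicate 1, 2 or 3 (adjusted p from 0.0506 to 0.0687). Of the 29 measured cellulose synthase and cellulose synthase-like genes, 5 rose, 7 fell and 17 did not pass (6 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.401). OsCslC9 (LOC4334258) and OsCslA1 (LOC4328585) rose by 1.57 (SE 0.17) and 1.30 (SE 0.09), and OsCslD1 and OsCesA9 fell most. Of the 10 measured genes of the xylem secondary wall, 2 rose, 4 fell and 4 did not pass (3 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.125). With OsCesA9, the other cellulose synthases of secondary walls, OsCesA4 (LOC4324625, -3.61, SE 0.16) and OsCesA7 (LOC4348853, -2.84, SE 0.21), singled out after their values were seen, fell, with OsBC1 as the fourth that fell. The risers of this list were OsIRX9 and OsBC1L2 (LOC4333115, 0.73, SE 0.17). OsBC1L2 lost its call with the replicate number as a block (adjusted p = 0.0846) and without uninfected root replicate 1, 2 or 3 or gall replicate 1, 2 or 3 (adjusted p from 0.0549 to 0.124). Of the 13 measured genes of root hair and epidermis, 0 rose, 2 fell and 11 did not pass (1 higher and 2 lower adjusted over the list alone, 2 and 2 at an unadjusted p under 0.05, camera adjusted p = 0.573). The pair that fell was OsCslD1 and OsRoc4 (LOC4336705), a homeobox factor of epidermal cells, which fell by 0.73 (SE 0.14). OsRoc4 lost its call without uninfected root replicate 1 or gall replicate 1 or 2 (adjusted p from 0.0677 to 0.0837). Of the 31 measured lignin and phenylpropanoid genes, 1 rose, 7 fell and 23 did not pass (3 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.125). OsLAC23 (LOC4351276) rose by 1.18 (SE 0.22), and OsCAD6 (LOC4335223, -2.03, SE 0.21) and OsROMT-17 (LOC4345935, -0.90, SE 0.17) fell. OsLAC23 lost its call without uninfected root replicate 1 or gall replicate 2 or 3 (adjusted p from 0.0734 to 0.0841). OsROMT-17 lost its call without uninfected root replicate 1 or gall replicate 1, 2 or 3 (adjusted p from 0.0544 to 0.0709).

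Single defence-related genes rose or fell, and no list of them passed camera. A test of whether a list's own genes moved on balance one way (fry) called some of these lists up. They were class III peroxidases (adjusted p = 0.00176), receptor-like kinases and NB-LRR genes (0.00466) and pathogenesis-related genes (0.00991). The WRKY, phytoalexin, salicylate and oxidase lists did not pass in fry (adjusted p from 0.226 to 0.457). Of the 35 measured pathogenesis-related genes, 8 rose, 4 fell and 23 did not pass (12 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.286). OsChib3H-a and OsChia2a rose most, and the germin-like genes OsGER3 (LOC4344838, -2.01, SE 0.27) and OsGER1 (LOC4344840, -1.65, SE 0.25) fell. Of the 17 measured genes of diterpenoid phytoalexin synthesis, 2 rose, 0 fell and 15 did not pass (2 higher and 0 lower adjusted over the list alone, 3 and 0 at an unadjusted p under 0.05, camera adjusted p = 0.366). Both risers, OsCYP99A3 (LOC4335091) with 2.31 (SE 0.44) and OsCYP71Z7 (LOC4329726) with 2.26 (SE 0.26), are cytochromes P450. The OsCYP71Z7 mean in uninfected root lay below the array medians, so the size of its rise is uncertain. OsCYP99A3 lost its call with the replicate number as a block (adjusted p = 0.0562) and without uninfected root replicate 1 or gall replicate 1 or 3 (adjusted p from 0.0532 to 0.0806). Of the 4 measured class III peroxidases, 2 rose, 1 fell and 1 did not pass (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.366). Changes went both ways, with rises of 3.28 (SE 0.10) for LOC4344277 and 1.01 (SE 0.19) for OsPRX112 (LOC4344279), while LOC4339222 fell by 1.80 (SE 0.23). OsPRX112 lost its call without uninfected root replicate 1 or gall replicate 2 or 3 (adjusted p from 0.0675 to 0.0776). Of the 9 measured receptor-like kinases and NB-LRR genes, 2 rose, 0 fell and 7 did not pass (5 higher and 0 lower adjusted over the list alone, 5 and 0 at an unadjusted p under 0.05, camera adjusted p = 0.151). OsCRK10 was followed by OsPIK6-NP (LOC4351153), a resistance-type gene, with 1.31 (SE 0.11). WRKY factors had 0 higher and 1 lower of 6 genes (0 and 1 adjusted over the list alone, 1 and 1 at an unadjusted p under 0.05, camera adjusted p = 0.557), with OsWRKY76 (LOC4347069) as the one that fell (-1.19, SE 0.26). Salicylate and NPR1-type genes had 0 higher and 2 lower of 19 genes (1 and 4 adjusted over the list alone, 4 and 6 at an unadjusted p under 0.05, camera adjusted p = 0.401). Among them, OsNPR4 (LOC4327365, -0.79, SE 0.12) fell most. Respiratory burst oxidases and glutathione transferases had 1 higher and 2 lower of 7 genes (1 and 3 adjusted over the list alone, camera adjusted p = 0.625), and OsrbohB (LOC4326027) rose by 1.66 (SE 0.11). OsWRKY76 lost its call with the replicate number as a block (adjusted p = 0.0905) and without uninfected root replicate 1, 2 or 3 or gall replicate 1 or 2 (adjusted p from 0.0558 to 0.123).

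Hormone genes also changed in both directions. Of the 69 measured auxin genes, 11 rose, 16 fell and 42 did not pass (15 higher and 20 lower adjusted over the list alone, camera adjusted p = 0.541). OsGH3-4 (LOC4339234), whose family conjugates auxin to amino acids, rose by 3.21 (SE 0.13, adjusted p = 8.91e-05), and OsARF2 (LOC4325895), an auxin response factor also named OsETTIN2, by 2.30 (SE 0.14, adjusted p = 0.000345). Besides OsILL3, OsIAA20 (LOC4340245), of the Aux/IAA repressors, fell by 3.21 (SE 0.15, adjusted p = 0.000137). Of the 31 measured cytokinin genes, 2 rose, 5 fell and 24 did not pass (4 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.401). OsCKX4 (LOC4326515), a cytokinin oxidase that degrades the hormone, rose by 2.61 (SE 0.19) and OsAHP1 (LOC4346300) by 0.66 (SE 0.10), and the response regulators OsRR1 (LOC4335937, -1.56, SE 0.24) and OsRR4 (LOC4325747, -1.33, SE 0.17), whose transcription cytokinin induces, fell. Of the 11 measured ethylene genes, 1 rose, 1 fell and 9 did not pass (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.366). OsACO1 was the riser, and OsACS2 (LOC4336750), an ACC synthase of the step before it, fell by 2.23 (SE 0.15, adjusted p = 0.000524). Of the 37 measured jasmonate genes, 9 rose, 2 fell and 26 did not pass (13 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.181). The JAZ repressor gene OsJAZ7 (LOC4347164) rose by 2.10 (SE 0.11, adjusted p = 0.000201) and the lipoxygenase gene OsLOX3 (LOC4333818) by 1.71 (SE 0.31). OsJAZ3 (LOC4331832) fell by 2.62 (SE 0.49) and OsAOS4 (LOC4328743) fell by 0.61 (SE 0.09). OsLOX3, also named r9-LOX1, was listed by its symbol alone, and a part of it in jasmonate synthesis was not tested. OsLOX3 lost its call without gall replicate 1, 2 or 3 (adjusted p from 0.0523 to 0.071). OsJAZ3 lost its call without gall replicate 2 or 3 (adjusted p from 0.0765 to 0.0817). Of the 34 measured genes of abscisic acid and dehydration, 4 rose, 4 fell and 26 did not pass (6 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.96). Osem (LOC4338499), a late embryogenesis gene, rose with OsRAB16D, by 3.41 (SE 0.16, adjusted p = 0.000131). OsABA8ox1 (LOC9269675, -1.10, SE 0.18), which degrades abscisic acid, and the kinase gene OsSAPK3 (LOC4349411, -0.97, SE 0.09) fell. OsABA8ox1 lost its call with the replicate number as a block (adjusted p = 0.0627). Gibberellin genes had 4 higher and 1 lower of 15 members (4 and 3 adjusted over the list alone, camera adjusted p = 0.598), with OsKS1A (LOC4336960) higher by 1.96 (SE 0.26). Means were under 4 in uninfected root for OsCKX4, Osem and OsKS1A and in galls for OsRR1, OsACS2 and OsJAZ3, which leaves the sizes of these changes uncertain.

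More genes of nutrient and water transport fell than rose in galls, among them phosphate, ammonium and silicon transporters. Of the 35 measured genes of nitrogen and phosphate transport and assimilation, 2 rose, 8 fell and 25 did not pass (3 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.0246). The list did not pass with an estimated correlation (adjusted p = 0.585), without uninfected root replicate 2 (0.0694) or without gall replicate 3 (0.0585). The phosphate transporter gene OsPht1;2 (LOC4331637, -1.53, SE 0.18) and the ammonium transporter gene OsAMT1 (LOC4336365, -1.19, SE 0.12) fell, and the risers were OsNAR2.2 (LOC4336175, 1.13, SE 0.16) and OsPht1;1 (LOC4331635, 0.51, SE 0.11). Both OsNAR2.2 means were under 4, and that of uninfected root (2.39) lay below the array medians, so the size of its rise is uncertain. OsPht1;1 lost its call with the replicate number as a block (adjusted p = 0.0963) and without uninfected root replicate 1 or gall replicate 1, 2 or 3 (adjusted p from 0.0842 to 0.13). Of the 25 measured aquaporin genes, 0 rose, 6 fell and 19 did not pass (1 higher and 10 lower adjusted over the list alone, 1 and 11 at an unadjusted p under 0.05, camera adjusted p = 0.0246). The list did not pass with an estimated correlation (adjusted p = 0.656), without uninfected root replicate 2 (0.0526) or without gall replicate 3 (0.104). OsNIP2-2 (LOC4340558), the silicon channel Lsi6, fell by 2.11 (SE 0.19) and OsTIP1-2 (LOC4324303) of the vacuolar membrane fell by 1.59 (SE 0.17). The OsNIP2-2 probe set is of a kind that can react with related transcripts. Of the 60 measured genes of iron, zinc and metal binding, 4 rose, 9 fell and 47 did not pass (5 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.115). The metallothionein genes OsMT2b (LOC4337596) and OsMT2a (LOC4325218) rose by 2.61 (SE 0.44) and 2.22 (SE 0.32), and the transporter genes OsVIT2 (LOC4346978, -1.60, SE 0.28) and OsZIP2 (LOC4333098, -1.55, SE 0.16) fell. OsMT2b lost its call without gall replicate 2 or 3 (adjusted p from 0.0545 to 0.0572). OsVIT2 lost its call with the replicate number as a block (adjusted p = 0.0624). Of the 32 measured genes of sugar transport and sucrose cleavage, 3 rose, 6 fell and 23 did not pass (3 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.366). The sucrose synthase genes OsSUS4 (LOC4332788) and OsSUS5 (LOC4335447) rose by 2.46 (SE 0.28) and 1.42 (SE 0.27), while the sugar exporter gene OsSWEET14 (LOC4350572, -1.11, SE 0.26) and the cell wall invertase gene OsCIN2 (LOC4335790, -0.91, SE 0.12) fell. OsSUS5 lost its call without gall replicate 1, 2 or 3 (adjusted p from 0.0594 to 0.0787). OsSWEET14 lost its call with the replicate number as a block (adjusted p = 0.0869) and without uninfected root replicate 1, 2 or 3 or gall replicate 3 (adjusted p from 0.056 to 0.146).

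Among lists named for other tissues, those of endodermis and phloem each had members that rose and members that fell. Genes were listed by symbol, and in which tissue they were transcribed was not tested. Genes of green tissue gave 0 higher and 1 lower of 12 genes (0 and 1 adjusted over the list alone, 1 and 1 at an unadjusted p under 0.05, camera adjusted p = 0.932), and OspetC (LOC4343570), of the photosynthetic electron chain, fell by 1.29 (SE 0.19). Endodermal genes gave 1 higher and 1 lower of 5 genes (1 and 3 adjusted over the list alone, camera adjusted p = 0.366), with OsSHR1 (LOC4343753, 0.61, SE 0.12) as the one that rose and OsSCR1 (LOC4349638, -1.10, SE 0.23) as the one that fell. The OsSCR1 mean in galls was under 4. OsSHR1 lost its call with the replicate number as a block (adjusted p = 0.0793) and without uninfected root replicate 1 or 2 or gall replicate 1 or 3 (adjusted p from 0.0647 to 0.111). OsSCR1 lost its call without uninfected root replicate 1 or gall replicate 1, 2 or 3 (adjusted p from 0.0575 to 0.0957). Phloem genes gave 1 higher and 1 lower of 8 genes (1 and 1 adjusted over the list alone, camera adjusted p = 0.932), where OsBRXL2 (LOC4330435, 0.67, SE 0.11) rose and the sucrose transporter gene OsSUT2 (LOC9266530, -0.61, SE 0.13) fell. OsBRXL2 lost its call with the replicate number as a block (adjusted p = 0.0532) and without gall replicate 2 or 3 (adjusted p from 0.0501 to 0.0513). OsSUT2 lost its call with the replicate number as a block (adjusted p = 0.0946) and without uninfected root replicate 1 or gall replicate 1 or 3 (adjusted p from 0.0708 to 0.118). Cytosolic ribosomal protein genes gave 1 higher and 1 lower of 26 genes (1 and 1 adjusted over the list alone, camera adjusted p = 0.541). Heat shock protein genes gave 4 higher and 1 lower of 27 genes (6 and 2 adjusted over the list alone, camera adjusted p = 0.402), among which OsHsp17.9A (LOC4332357) rose by 2.08 (SE 0.30) and OsHsp23.2 (LOC4335956) fell by 3.69 (SE 0.25). Genes of hypoxia and fermentation gave 0 higher and 0 lower of 7 genes (0 and 0 adjusted over the list alone, 2 and 0 at an unadjusted p under 0.05, camera adjusted p = 0.557), and pectin-modifying enzymes gave 0 higher and 0 lower of 4 genes (0 and 1 adjusted over the list alone, 0 and 1 at an unadjusted p under 0.05, camera adjusted p = 0.402). OsXTH8 (LOC4345019), a xyloglucan endotransglucosylase gene, fell by 1.09, and the log2 difference of OsproT (LOC4333560), a proline transporter gene, was -0.075 and did not pass. Each was the single member with a matching symbol or synonym in a list too short to test, and the root cap list had 0 such members.

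**Figure D2:**
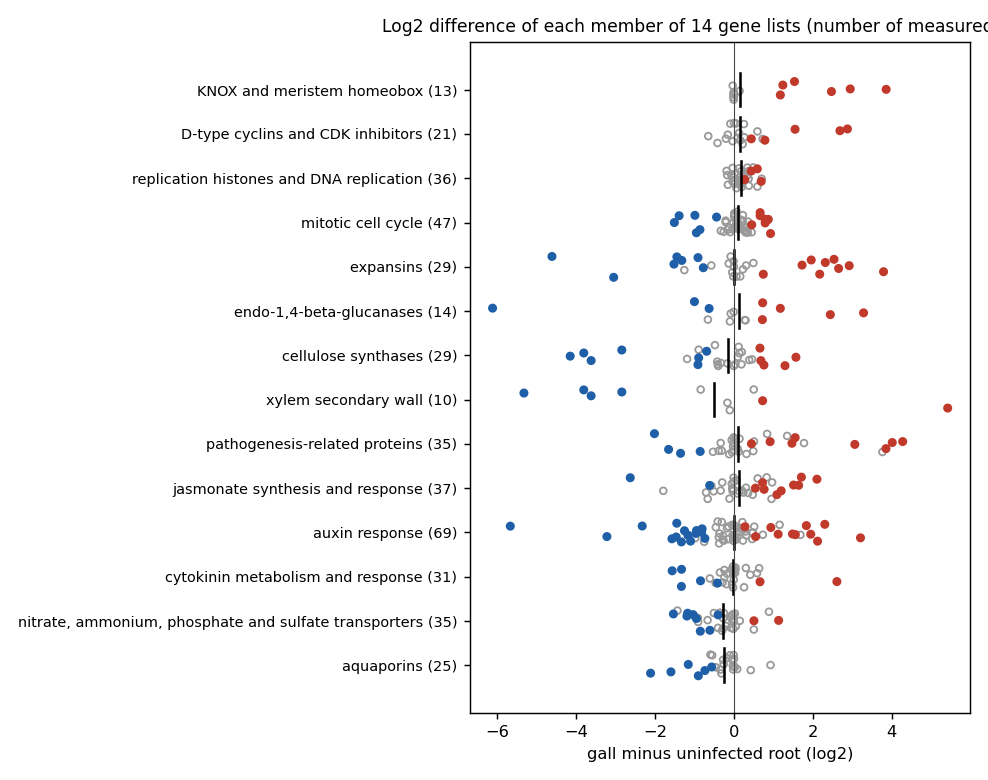
Log2 difference, gall minus uninfected root, of each measured member of 14 gene lists, with the number of members in brackets. Filled red and blue circles are genes higher and lower in galls at an adjusted p under 0.05 (limma), open grey circles are genes that did not pass, and black bars are list medians, which lie between -0.50 and 0.17.

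Of the 34 lists tested, 2 were shifted up and 2 down in galls at an adjusted p under 0.05 in camera. The preset correlation was 0.01, and each of the 4 had an adjusted p of 0.0246. Of the 10 splits of the 6 arrays into 3 and 3, 5 called 4 or more lists, the real split among them. Another split called 9, so the number of called lists does not set the real groups apart. With an estimated correlation 0 of the 34 lists passed in camera, and 1 up and 1 down had an unadjusted p under 0.05. The count was also 0 up and 0 down without uninfected root replicate 2 (5 up and 4 down at an unadjusted p under 0.05) or without gall replicate 3 (5 and 5). Estimated correlations were -0.00928 for KNOX and WOX genes and -0.00988 for nitrogen and phosphate transport, both below the preset 0.01. They were 0.0771 for replication genes and 0.059 for aquaporins. A higher correlation is thus not why the first 2 of these lists lost their call. Their unadjusted p in camera went from 0.00289 and 0.00203 to 0.0344 and 0.0233. With an estimated correlation, camera takes its degrees of freedom from the 6 arrays, far fewer than with a preset one. This raises p-values, so a call can be lost there without a higher correlation. The part of each in the loss of the other 2 lists was not tested. A test of whether a list's own genes moved on balance one way (fry) gave 9 up and 8 down. The lists up were replication, D-type cyclins, KNOX and WOX, expansins, endoglucanases, peroxidases, pathogenesis-related, jasmonate, and receptor-like kinase and NB-LRR genes. The lists down were cellulose synthases, lignin, sugar transport, nitrogen and phosphate transport, aquaporins, endodermis, xylem secondary wall and root hair. The median, the mean and the test of a list differed in sign for expansins (median -0.000811, mean 0.22, camera up), ethylene synthesis and signalling (median -0.16, mean 0.00313, camera down) and gibberellin metabolism and response (median -0.0105, mean 0.27, camera up).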

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

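The test of the fungal probe sets was chosen after the result was seen. The array carries 123 control probe sets, which entered no comparison. In 7 of them all 3 gall arrays lay above all 3 uninfected root arrays and in 7 all lay below, and chance separates 10% of probe sets in this way, or 12.3 of 123. The rice glyceraldehyde-3-phosphate dehydrogenase controls were higher in galls by 0.48, 0.47 and 0.45 for the 3', middle and 5' probe sets, and the rice ubiquitin controls by 0.40, 0.38 and 0.29 for the 5', middle and 3' probe sets. Of the 7 lower in galls, 2 were the rice 25S and 18S ribosomal RNA probe sets (-0.84 and -0.45), and the 25S difference was -0.47 without gall replicate 3. Another 3 were rice actin probe sets, the middle one of one set and the 5' and 3' ones of another (-0.43, -0.42 and -0.25). Without uninfected root replicate 3 their differences were -0.28, -0.24 and -0.12. The remaining rice actin probe sets had lower means in galls but did not separate the groups. The last 2 of the 7 were controls of the bacterial thr gene (-0.57 and -0.30). The larger of these was -0.32 without gall replicate 3 and the smaller -0.18 without uninfected root replicate 2. The rice actin 3' minus 5' difference was 3.22, 3.38 and 3.14 in uninfected root replicates 1, 2 and 3, and higher in galls (3.39, 3.47 and 3.40). The margin between 3.38 and 3.39 is narrow, and in the array's other rice actin set this difference did not separate the groups. That of glyceraldehyde-3-phosphate dehydrogenase did not separate the groups (2.51, 2.58 and 2.14 against 2.39, 2.53 and 2.38). Whether RNA quality differed was not tested.

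A probe set made for the elongation factor gene ef1a of the rice blast fungus Magnaporthe was higher in every gall array, by 0.68 (mean 5.31 in uninfected root, 5.99 in galls), and by 0.23 without uninfected root replicate 3. Nematode RNA could react with probes made for another species. The 10 probe sets for that fungus had a median difference of 0.00105 (from -0.07 to 0.68), but only 3 of them reached a mean of 4, so the test leaves this open. Those 3 were higher in galls on average (0.16, 0.49 and 0.68), and in each of them uninfected root replicate 3 was the lowest of the 6 arrays. Rice transcripts of the same family were not tested as a source.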

How the results depend on the processing

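No call changed direction under any alternative, and all alternatives were planned, though the method of estimating array weights was changed when the default did not converge. Without moderation 1230 probe sets were higher and 880 lower (711 and 540 by at least 2-fold), with array weights 6414 and 5377 were, and with 1 probe set per gene 892 and 826 differed by at least 2-fold. The last count tests fewer probe sets by construction, and the cause of the others was not tested. Leaving out 1 array or 1 replicate number gave 1347 to 3387 higher and 1154 to 3479 lower, with the lowest counts without replicate 1 and the highest without uninfected root replicate 3, and the cause was not tested. Gene lists shifted up numbered 0 with an estimated correlation, 9 with fry and 1 among genes with a mean of at least 4, where replication genes had an adjusted p of 0.0695, and 0 to 2 without 1 array. Lists shifted down numbered 0 with an estimated correlation, 8 with fry and 0 to 3 without 1 array. With the replicate block, 1983 probe sets were higher and 1633 lower, of which 1838 and 1509 were called without it too. The block ended 31 of the 142 calls of named genes, given beside the genes described, and changed no other call of a gene or list described. Of those 142 calls, 98 held in every fit without 1 array and 44 were lost in 1 or more such fits. The higher share of calls was 54.5%, and 54.3% and 51.9% with quantile normalisation and median centring. Signal near background limits the 34934 probe sets with a mean under 4.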

Other observations

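The tests of the falls, of auxin response factors as a class and of splits of probe set counts were chosen after the results were seen, while the other tests of lists and splits were not. HD-ZIP genes of class III, which pattern meristems and vascular tissue, were singled out after their values were seen, and 4 of 5 rose. OsHox33 (LOC4352777, 1.98, SE 0.16), OsHox32 (LOC4333544, 1.38, SE 0.14), OsHox9 (LOC4348919, 1.21, SE 0.11) and OsHox10 (LOC4331345, 1.15, SE 0.11) rose, and OsHox29 (LOC4327348, -1.47, SE 0.15) fell. Of the 25 measured HD-ZIP genes, 7 rose, 2 fell and 16 did not pass (10 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.76). The MADS-box genes OsMADS16 (LOC4342047, 3.07, SE 0.34) and OsMADS2 (LOC4325001, 2.14, SE 0.19), known from floral organ identity, rose, with 3 higher and 3 lower of 31 MADS-box genes (3 and 3 adjusted over the list alone, camera adjusted p = 0.957). In uninfected root the OsMADS2 mean (2.67) lay below the array medians and that of OsMADS16 was under 4, so the sizes of these rises are uncertain. Of the 77 measured genes of calcium sensors and their kinases, 6 rose, 20 fell and 51 did not pass (6 higher and 32 lower adjusted over the list alone, camera adjusted p = 0.00211). The list did not pass with an estimated correlation (adjusted p = 0.111). The calmodulin-like gene OsCML31 (LOC4325408, -2.82, SE 0.40) fell most and OsCBL4 (LOC4339432, 3.53, SE 0.43) rose most. This was the only one of the 11 added lists called, with an adjusted p of 0.000764 to 0.00523 without 1 array.

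Of the 38 measured cytoskeleton genes, 2 rose, 10 fell and 26 did not pass (4 higher and 13 lower adjusted over the list alone, camera adjusted p = 0.174). OsADF9 and OsADF1 fell most, and the formin gene OsFH15 (LOC4347588, 2.26, SE 0.14) rose most. Beta-glucosidases had 5 higher and 5 lower of 27 genes (6 and 6 adjusted over the list alone, camera adjusted p = 0.957), with OsBGLU26 (LOC4344146, 2.74, SE 0.20) as the largest rise, from a mean under 4. Thioredoxins and glutaredoxins had 4 higher and 4 lower of 31 genes (8 and 5 adjusted over the list alone, camera adjusted p = 0.957), led by OsGRXS3. PP2C phosphatases had 6 higher and 1 lower of 55 genes (8 and 2 adjusted over the list alone, camera adjusted p = 0.957), with OsPP2C33 (LOC4332577, 1.79, SE 0.13) highest. Heat shock factors had 2 higher and 0 lower of 20 genes (4 and 0 adjusted over the list alone, 5 and 1 at an unadjusted p under 0.05, camera adjusted p = 0.203), potassium transporters 1 higher and 1 lower of 22 genes (1 and 1 adjusted over the list alone, camera adjusted p = 0.215), growth-regulating factors 0 higher and 3 lower of 10 genes (0 and 3 adjusted over the list alone, 1 and 4 at an unadjusted p under 0.05, camera adjusted p = 0.61) and SPL factors 2 higher and 0 lower of 12 genes (3 and 0 adjusted over the list alone, 3 and 0 at an unadjusted p under 0.05, camera adjusted p = 0.888). Among the added lists, median, mean and test differed in sign for family 1 beta-glucosidases (median 0.0178, mean -0.0444, camera up), MADS-box factors (median -0.00866, mean 0.14, camera down), HD-ZIP homeobox factors (median -0.0327, mean 0.26, camera up), clade-numbered PP2C phosphatases (median -0.00439, mean -0.01, camera up), thioredoxins and glutaredoxins (median -0.00481, mean 0.16, camera up) and SPL factors (median -0.00218, mean 0.11, camera up).

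The 4 auxin response factor genes that the small RNA tasiR-ARF is known to cleave rose together, with OsARF2 (2.30, SE 0.14), OsARF15 (LOC9268260, 2.12, SE 0.12), OsARF14 (LOC4339313, 1.95, SE 0.10) and OsARF3 (LOC4327014, 1.84, SE 0.20). The other 12 measured members had a median difference of 0.13 (from -1.16 to 1.49), and 2 of them passed as higher and 1 as lower. This argued against a rise of every member of the class. The 4 lay above the other 12 (exact permutation p = 0.000549, two-sided, 1820 ways). Lower transcript levels were argued against only for 3 genes of the pathway that makes this small RNA, while its other genes, AGO7 among them, have no probe set of that name here. In that test, set before its values were seen, OsDCL4 (LOC4336362, 0.79, SE 0.18), OsSHL2 (LOC4323938, 0.61, SE 0.16) and OsSGS3 (LOC4351724, 0.36, SE 0.11) had a median of 0.61, with 1 of the 3 passing as higher and 0 as lower in limma (0 also at an unadjusted p under 0.05). The 3 were named after their values were seen. OsDCL4 lost its call with the replicate number as a block (adjusted p = 0.127) and without uninfected root replicate 1 or gall replicate 1, 2 or 3 (adjusted p from 0.0745 to 0.138). The level of tasiR-ARF itself and the transcription of these 4 genes were not measured, so why they rose stays open. The OsARF14 mean in uninfected root was under 4. The 4 were picked because they rose, which by itself lowers the median of the other 12. The permutation p therefore describes these data and is no independent test.

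The falls of actin depolymerising factors, OsCslD1 and secondary wall genes could come from the sampled zone of the root or from a single array. The named genes with the 10 largest falls did not rest on uninfected root replicate 3 alone. Of these falls, 10 of 10 passed without that array, with a median size of 4.82. The rule that selected these genes required a fall in all 3 same-numbered pairs, which favours this result, so it is no independent test. A larger part of hair-bearing or xylem-forming root in the uninfected fragments stays open. The root hair and xylem lists had 16 members with a mean of at least 4 in the higher group. Of these, 6 fell (37.5%) and 2 rose, which neither meets nor excludes the explanation. OsCslD1, OsCesA9 and OsBC1 are among those 6 and also among the falls to be explained. The share is thus partly drawn from the pattern itself and is lower without them, so it cannot decide. The nematode's own effect on these cell types was not tested apart from the sampled zone, because gall and zone go together in this design.

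The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Of these, 1 split, the real one, gave as many as 5371 called probe sets (2613 by at least 2-fold), and the highest other gave 0 in limma. The split of uninfected root 1, gall 1 and gall 2 from the rest had 13370 probe sets at an unadjusted p under 0.05 against 11346 in the real split, and 0 after adjustment. The 3 other splits that part all 3 pairs called 0 probe sets, with at most 675 at an unadjusted p under 0.05. For gene lists the real split gave 4, the highest other 9, and 5 of the 10 splits gave 4 or more. The number of called lists thus does not set the real split apart. The split with 9 set uninfected root 1 and 2 with gall 1 against the rest, for a reason that was not tested, and the highest among those that part all pairs gave 5.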
